A study of Mus musculus with 26 samples.

How the data were processed

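RNA was measured in the accumbens nucleus of Drd2-TRAP mice: 24 libraries of polysome RNA immunopurified with antibodies against EGFP and 2 libraries of total input RNA. Each deposited file gives raw read counts per gene symbol for 1 library, in whole numbers and not normalized. Per the submitters' processing notes, STAR 2.0.0e, HTSeq and the mouse build mm10 were used by the authors; the HTSeq version, gene annotation and strand setting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes therefore cannot be told apart. The 5 HTSeq summary rows and a row named unknown (at most 1 count) were left out of library sizes and tests. Reads in genes made up 13.7% to 48.6% of the records of an immunopurified library (median 28.5%), reads in no feature 29.7% to 62.5%, and reads with several alignments 6.52% to 41.2%. The files of library set 1 list 32657 genes and those of set 2 list 32531; the 31735 shared genes, which hold 99.0% to 99.3% of the gene counts of immunopurified libraries, were used.

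Groups and replicate numbers come from the sample titles. Counts in genes per immunopurified library ran from 1.54 to 17.5 M (M for 1e6 counts), and 3 counts correspond to 0.198 to 2.19 CPM (counts per M), so genes at a few CPM rest on few counts in the shallow libraries. Libraries of 1 group were compared pairwise: the lowest chi-square per degree of freedom was 19.0 over 57 pairs, far above sampling noise, so no pair of 1 group is the same library sequenced again. That leaves open whether 2 libraries came from 1 animal. Replicate numbers 1 to 3 of saline withdrawal and 1, 2 and 4 of nonescalating withdrawal occur in both library sets. Between the sets, Pearson r was 0.756 to 0.871 in the 6 pairs of 1 group with the same number and 0.715 to 0.887 in the 18 pairs with other numbers. Each library was counted as 1 replicate, so n = 6 and n = 8 are counts of libraries.

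Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main test was edgeR's quasi-likelihood test with robust dispersions, TMM factors, filterByExpr with a minimum count of 10, and Benjamini-Hochberg adjustment with a threshold of 0.05. The 24 immunopurified libraries were fitted together with group and library set as terms, which gives 7 comparisons over 15854 genes. The saline and nonescalating groups without withdrawal lie in library set 1 only, so the set term is estimated from the withdrawal groups alone. Immunopurified RNA was compared with input in a separate fit of 8 immunopurified and 2 input libraries with agent as a term, over 14929 genes. Standard errors are the size of the log2 fold change divided by the square root of the F statistic. Levels are CPM with TMM factors, and list scores are mean log2 CPM with a prior count of 2.

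Of 39 gene lists fixed before the data were examined, 37 with at least 4 tested genes were tested in each comparison with camera (preset correlation 0.01), adjusted over lists within a comparison. The lists of mitochondrially encoded genes (0 genes in the files) and red blood cell genes (3 genes) were not tested. Alternatives were camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance in 1 direction. Named genes follow a rule fixed at the same time: the 12 genes with the smallest p in each direction among those that passed with a mean log2 CPM of at least 2 and no predicted symbol, or the 5 with the smallest p where fewer than 5 passed, up to 4 members of each list that passed, and Drd2, Adora2a, Penk, Drd1, Tac1, Fos and Chat. Given after their values were seen are Izumo1, as 1 of 2 calls by DESeq2, Ebf1, as a gene that passed against the direction of its list, Mbp and Ndrg2 in saline animals and for the difference, and Hdac5 in the cocaine effects behind the difference. Over all comparisons the rule allows 12 genes that passed, all higher, 35 by smallest p (15 higher, 20 lower) and 168 list members (80 higher, 88 lower). The rule names no list member for going against its list, so Ebf1 is an addition to it. Only part of these are printed, and 1 of them is not reported here.

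Alternatives chosen with the design were DESeq2's Wald test, limma voom with sample quality weights, median-of-ratios scaling, no filter or a stricter filter on low counts (CPM of at least 1), only the groups compared, a covariate of non-neuronal markers, the replicate number as a block, no library set term, each library set alone, the nonescalating libraries against saline withdrawal of set 1 because of the conflict in their labels, and each library left out in turn. Chosen after seeing the data were a covariate of vascular markers, all 24 or the 16 set 1 immunopurified libraries against input, list tests with single libraries left out, with the block or within a library set, and leaving out libraries 1806, 1813 and 1843, which had the lowest median correlations with other immunopurified libraries. Other splits of the libraries were fitted up to 100 times per comparison, within library sets. Gene length, GC content and positions come from GENCODE M21.

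Before use, the tests were run on simulated counts drawn with the means, library sizes and dispersions of these libraries and 200 changed genes. The changed genes were drawn among those with a mean log2 CPM of at least 2, and no difference between library sets was simulated. Recovery among lower genes was not simulated. Of 50 genes changed 2-fold, edgeR recovered 0% in immunopurified against input RNA and 0% in escalating against saline. For immunopurified against input RNA, edgeR recovered 4% of 50 genes changed 4-fold, 28% of 50 changed 8-fold and 52% of 50 changed 16-fold, with 2 false calls among 44. In escalating against saline the shares were 12%, 24% and 48%, with 2 false calls, and a simulated list of 20 genes shifted 2-fold was not called there (adjusted p = 0.522), while it was called in the other 3 comparisons simulated. None of 40 unshifted lists was called in any of the 4; these simulations draw genes independently, so they do not test the effect of correlated genes.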

Results

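The dataset holds 26 RNA-seq libraries from the accumbens nucleus, a ventral striatal region of the reward circuit, of adult mice that took cocaine or saline by intravenous self-administration with long access. The mice carry the Drd2-TRAP transgene of line CP101, which puts an EGFP tag on ribosomal protein L10a in cells that use the Drd2 promoter. In the accumbens these are mainly the medium spiny projection neurons with dopamine D2 receptors, and also cholinergic interneurons. Polysomes were pulled down with an antibody against EGFP and their RNA was sequenced (24 immunopurified libraries), and total RNA was sequenced as input in 2 libraries. By their titles the immunopurified libraries form 5 groups: saline (n = 3), cocaine without escalation of intake, called nonescalating (n = 5), cocaine with escalation, called escalating (n = 2), saline followed by withdrawal (n = 6), and nonescalating followed by withdrawal (n = 8). The inputs are 1 saline and 1 nonescalating library. The description field of the 5 nonescalating libraries carries the word withdrawal while their titles do not, and the groups here follow the titles. Library numbers and index numbers form 2 runs, called library set 1 (numbers up to 1825) and library set 2 (from 1836), and only the withdrawal groups occur in set 2. Replicate numbers of the withdrawal groups repeat between the sets, and nothing in the labels says whether each library is 1 animal. Thus n counts libraries, and p-values measure the spread between these libraries. The comparison with input has 1 input per agent, so its spread is assumed to be that of the immunopurified libraries. Its p-values therefore tell little of the spread among inputs.

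Total counts in genes ranged from 1.54 to 17.5 M per immunopurified library (median 3.27 M, n = 24) and were 4.70 M in the saline input and 37.5 M in the nonescalating input. Mean totals were 5.91 M ± 3.25 (SD, n = 3) in saline, 4.0 M ± 3.23 (SD, n = 5) in nonescalating, 12.6 M ± 6.98 (SD, n = 2) in escalating, 4.40 M ± 3.48 (SD, n = 6) in saline withdrawal and 5.37 M ± 4.65 (SD, n = 8) in nonescalating withdrawal. Between 12124 and 17058 genes had at least 1 count in an immunopurified library. Pearson correlations of log2 CPM between libraries of 1 group ran from 0.715 to 0.899 over 57 pairs, and no pair of libraries differed by as little as sampling noise. In the lead marker of the tagged cells, the dopamine receptor gene Drd2 (chromosome 9, 49340627 to 49408177, plus strand, mm10), the groups had overlapping levels: 2097 CPM ± 669 (SD, n = 3) in saline, 1662 ± 931 (SD, n = 5) in nonescalating, 2665 ± 475 (SD, n = 2) in escalating, 2207 ± 735 (SD, n = 6) in saline withdrawal and 1914 ± 569 CPM (SD, n = 8) in nonescalating withdrawal. The inputs had 279 and 392 CPM. One immunopurified library, nonescalating replicate 4 (library 1813), had 243 CPM of Drd2, below both inputs, with 76828 CPM of the nuclear RNA Malat1. All libraries had counts of the Y-linked gene Ddx3y.

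The first comparison asks which RNAs the pull-down enriched, with 8 immunopurified libraries without withdrawal (3 saline, 5 nonescalating) against the 2 inputs. Among the genes that passed was Myh11, the smooth muscle myosin heavy chain (chromosome 16, 14194535 to 14291372, minus strand), with 115 CPM ± 76.0 (SD, n = 8) against 0.0672 CPM in the inputs (log2 fold change 9.75, SE 1.24, adjusted p = 0.00452). The mean of the inputs lies below the level of 3 counts, 0.601 CPM in the saline input and 0.0828 CPM in the nonescalating input. The size of the Myh11 fold change thus rests on few input counts. Hspg2, which encodes the basement membrane proteoglycan perlecan, had a log2 fold change of 4.89 (SE 0.79, adjusted p = 0.0187), and Rgs5, a pericyte marker, one of 4.25 (SE 0.82, adjusted p = 0.0395). Other genes that were higher in all 8 libraries than in both inputs were Gata2, an endothelial and blood transcription factor gene (4.91, SE 0.72, adjusted p = 0.0172), Osmr, the oncostatin M receptor gene (6.07, SE 0.93, adjusted p = 0.0172), and Nes, which encodes the intermediate filament nestin (4.30, SE 0.70, adjusted p = 0.0189). All 13 genes of the endothelial and mural list had positive fold changes, with a median of 3.91, though the list did not pass in fry (adjusted p = 0.059) or in camera with an estimated correlation (0.0986). The endothelial genes Flt1 (3.94, SE 0.82) and Pecam1 (3.84, SE 0.88) missed the threshold, with adjusted p = 0.059 and 0.072.

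Of the tagged neurons' markers, Drd2 had 1826 CPM ± 826 (SD, n = 8) against 331 CPM in the inputs, a log2 fold change of 2.46 (SE 0.71, adjusted p = 0.171), and was above both inputs in 7 of 8 libraries. The adenosine receptor gene Adora2a had a log2 fold change of 1.77 (SE 0.73, adjusted p = 0.48), and Penk, the enkephalin precursor gene, one of 1.71 (SE 0.76, adjusted p = 0.546). All 10 genes of the D2 neuron list had positive fold changes (median 1.88). The D1 neuron list had a median of -1.88, with 8 of 10 genes below 0. The dopamine D1 receptor gene Drd1 had 32.1 CPM ± 16.8 (SD, n = 8) against 136 CPM (log2 fold change -2.08, SE 0.56, adjusted p = 0.128), and Pdyn, the dynorphin precursor gene, had -2.19 (SE 0.57, adjusted p = 0.113). Ebf1, also a D1 neuron list member and a transcription factor gene used by several cell types, went the other way and passed (3.17, SE 0.60, adjusted p = 0.0355). Oligodendrocyte genes had a median of -2.28 with 12 of 13 below 0, for example Trf, the transferrin gene, at -2.51 (SE 0.55, adjusted p = 0.0658). All 8 GABA interneuron genes were below 0 (median -2.42), among them Lhx6 at -2.55 (SE 0.67, adjusted p = 0.116). Genes of cholinergic interneurons, which also use Drd2, had a median of -1.45 with 8 of 9 below 0. Chat, the acetylcholine synthesis gene, had 7.18 CPM ± 8.24 (SD, n = 8) against 14.5 CPM, a log2 fold change of -1.11 (SE 1.62, adjusted p = 0.998). The noncoding RNAs Meg3 (-1.88, SE 0.43, adjusted p = 0.072) and Rian (-1.93, SE 0.44, adjusted p = 0.0714) were below both inputs in 8 of 8 libraries. The nuclear RNA Malat1 did not share this. It had 22965 CPM ± 14030 (SD, n = 3) in saline and 31058 ± 27056 (SD, n = 5) in nonescalating. The inputs had 21956 and 10386 CPM of it, within the range of the immunopurified libraries (7452 to 76828 CPM). The chromosome positions are those of mouse build GRCm38, to which mm10 corresponds, in the GENCODE M21 annotation.

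**Figure D1:**
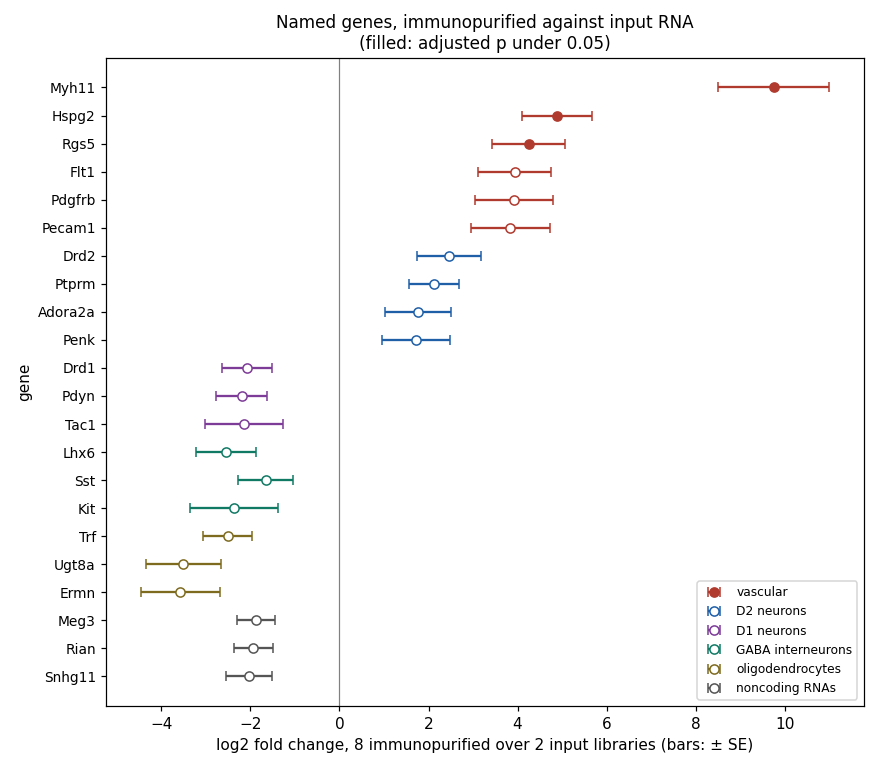
Log2 fold change (x axis) of named genes (y axis) in 8 immunopurified libraries over 2 inputs, with bars for ± 1 SE and filled points for genes with an adjusted p under 0.05. Of the genes plotted, Myh11 lies furthest to the right at 9.75, while Drd2 lies at 2.46 and Trf at -2.51.

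In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 38 of 14929 genes passed an adjusted p of 0.05, all 38 higher in the immunopurified libraries, and 1234 genes had an unadjusted p under 0.05. In camera's list test with a preset correlation, 17 of 37 lists passed, 4 higher and 13 lower. The higher lists were the endothelial and mural genes (adjusted p = 1.85e-21), interferon and immune genes (2.69e-12, median log2 fold change 3.40), D2 neuron genes (5.37e-06) and cytosolic ribosomal protein genes (0.00037, median 0.50). None of the 17 held with an estimated correlation: the adjusted p was then 0.0986 for the endothelial and mural, oligodendrocyte and GABA interneuron lists, 0.181 for the D2 neuron and immune lists, 0.164 for the D1 neuron and cholinergic lists, 0.312 for the nuclear RNAs that include Meg3 and Rian, 0.542 for the ribosomal protein list, and at most 0.588 for the others. The test fry called 5 lists, all lower: lipid synthesis (adjusted p = 0.00524), GABA interneuron (0.00666), oligodendrocyte (0.0264), D1 neuron and cholinergic genes (0.0377 each). It did not call the endothelial and mural list (0.059). Adjusted over the list alone, 11 of 13 vascular, 12 of 17 immune, 3 of 10 D2 neuron and 8 of 13 oligodendrocyte genes passed. The test rests on 2 inputs: without either input 1 gene passed, and without the nonescalating input 11 lists passed. DESeq2 called 757 genes, 712 higher and 45 lower, of which 80 had no count in 1 of the groups. Without nonescalating replicate 4, Drd2 passed, with a log2 fold change of 2.63 and an adjusted p of 0.0203, and 45 genes passed. The count was 252 without saline replicate 3, 148 without nonescalating replicate 3, 24 without saline replicate 4 and 20 without nonescalating replicate 5.

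**Figure D2:**
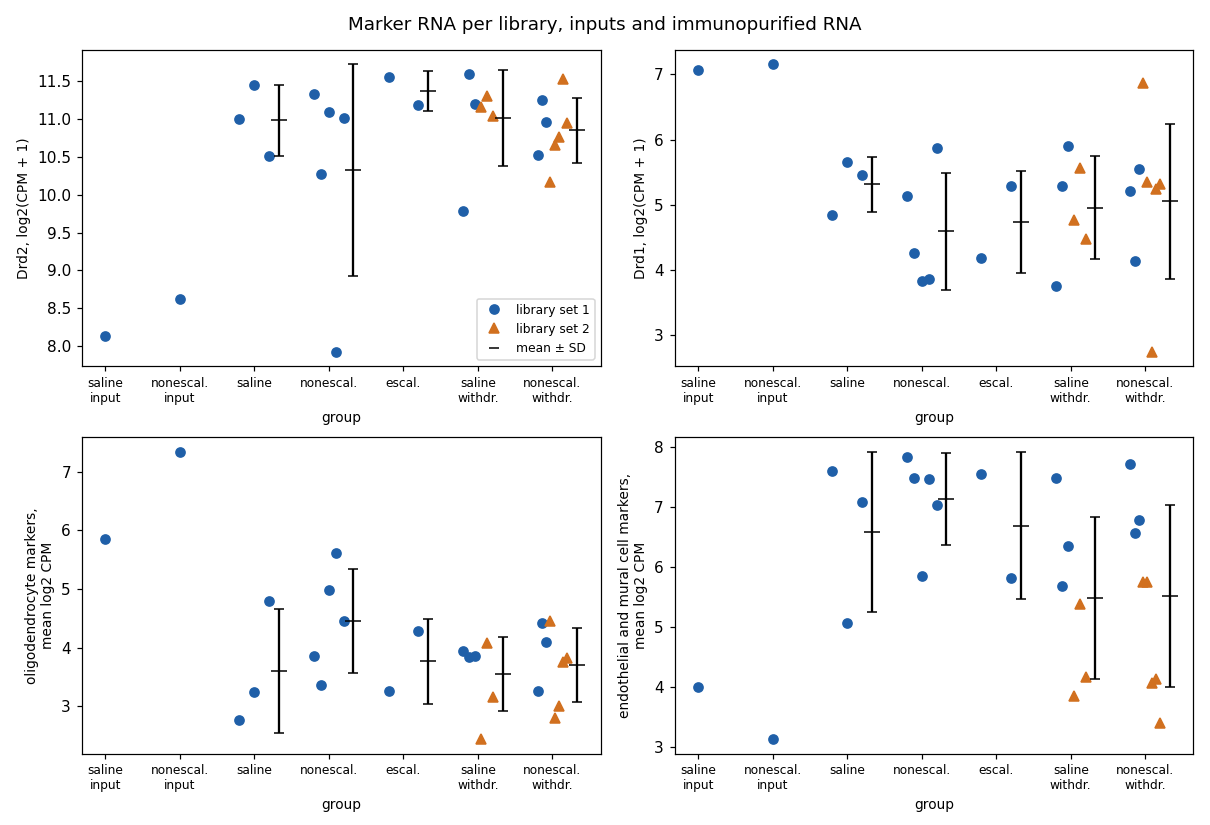
Marker RNA per library (1 point each) by group, as log2(CPM + 1) for Drd2 and Drd1 and as mean log2 CPM for the oligodendrocyte and the endothelial and mural lists; circles are library set 1, triangles library set 2, and black bars give the mean ± SD of groups with more than 1 library. Drd2 lies above both inputs in all immunopurified libraries except nonescalating replicate 4, and the vascular list lies between 5.07 and 7.84 in set 1 and between 3.39 and 5.75 in set 2, with the inputs at 4.0 and 3.13.

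The next comparison asks how RNA in Drd2 cells differs after cocaine without escalation, nonescalating (n = 5) against saline (n = 3). No gene passed. The genes with the smallest p were Ubr7, an E3 ubiquitin ligase gene, at 10.3 CPM ± 4.38 (SD, n = 5) against 76.8 ± 30.3 (SD, n = 3), with a log2 fold change of -2.91 (SE 0.62, adjusted p = 0.506), and Aars, an alanyl-tRNA synthetase gene, at 49.9 CPM ± 26.5 against 210 ± 127, with -2.07 (SE 0.45, adjusted p = 0.506). Spata2 (-2.44, SE 0.57), Ralgds, which encodes an exchange factor for Ral GTPases (-1.85, SE 0.44), and Fam149a (5.50, SE 1.30) each had an adjusted p of 0.609. Of 16 markers shared by medium spiny neurons, 14 had negative fold changes (median -0.23), the lowest p being that of Rarb, a retinoic acid receptor gene (-1.86, SE 0.54, adjusted p = 0.719). Of 13 oligodendrocyte genes, 11 had positive ones (median 0.68), as for Mal (1.21, SE 0.57, adjusted p = 0.719).

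edgeR called 0 of 15854 genes, with 1068 at an unadjusted p under 0.05 (smallest adjusted p 0.506). limma voom called 0 and DESeq2 34, of which 18 had no count in 1 of the groups. Both lists passed camera at an adjusted p of 0.0401, which became 0.799 for the shared neuron markers and 0.764 for the oligodendrocyte genes with an estimated correlation. Neither call held without nonescalating replicate 4 (0 lists), the library with low Drd2, nor without saline replicate 3 (0 lists), where the shared neuron median turned to 0.33. The count was 15 without nonescalating replicate 3, 12 without its replicate 1 and 1 without its replicate 2, 13 without saline replicate 1 and 6 without saline replicate 4.

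For escalation of intake, escalating (n = 2) was compared with saline (n = 3) and with nonescalating (n = 5). Against saline no gene passed: Cpne1, a copine gene, had 190 CPM ± 214 (SD, n = 2) against 9.89 ± 5.75 (SD, n = 3), a log2 fold change of 4.27 (SE 0.95, adjusted p = 0.614). Without escalating replicate 1, the log2 fold change of Cpne1 in escalating vs saline was 1.95 (adjusted p = 0.703). Rara, a retinoic acid receptor gene, had 0.804 CPM ± 0.116 against 41.1 ± 18.6, a log2 fold change of -5.64 (SE 1.30, adjusted p = 0.614). Pard6g, a cell polarity gene, had 1314 CPM in escalating replicate 1 and 0.295 CPM in escalating replicate 2, so its fold change of 7.31 (SE 1.74, adjusted p = 0.614) came from 1 library. Against nonescalating, Ap2a1 (chromosome 7, 44900373 to 44929496, minus strand), which encodes a subunit of the clathrin adaptor AP-2, had the smallest p, with a log2 fold change of 6.15 (SE 1.0, adjusted p = 0.057). It too came from 1 library: 10127 CPM in escalating replicate 2 and 81.8 CPM in escalating replicate 1, against 72.0 CPM ± 28.8 (SD, n = 5). Rgs17, a G protein signalling regulator gene, differed in both escalating libraries, with 323 CPM ± 15.1 (SD, n = 2) against 101 ± 44.0 (SD, n = 5) and a log2 fold change of 1.67 (SE 0.38, adjusted p = 0.442).

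Among lists against nonescalating, 15 of 16 shared medium spiny neuron markers had positive fold changes (median 0.55), as for Ppp1r1b, the DARPP-32 gene (1.05, SE 0.56, adjusted p = 0.56). Of 73 nuclear genes of oxidative phosphorylation 54 were above 0 (median 0.43), as for Uqcrc1 (1.89, SE 0.55, adjusted p = 0.558), and of 15 opioid and neuropeptide genes 12 (median 0.67), as for Cartpt, the CART peptide gene (2.25, SE 0.89, adjusted p = 0.558). Of 25 immediate early genes, which neurons induce with activity, 19 were above 0 (median 0.23), led by Dusp1 (1.87, SE 0.54, adjusted p = 0.558), Nr4a3 (2.45, SE 0.97) and Egr1 (1.03, SE 0.48). Of 29 potassium channel genes 20 were above 0 (median 0.41), among them Kcnq5 (1.38, SE 0.46) and Kcna1 (1.19, SE 0.43). Astrocyte genes went the other way, with 13 of 14 below 0 (median -0.92), as for Gja1, the connexin 43 gene, at 0.558 CPM ± 0.0467 (SD, n = 2) against 18.6 ± 11.9 (SD, n = 5).

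edgeR called 0 of 15854 genes in both, with 1283 (against saline) and 1388 (against nonescalating) at an unadjusted p under 0.05. DESeq2 called 143 and 225, of which 59 and 104 had no count in 1 of the groups. limma voom called 0 and 8. Camera called 0 lists against saline and 12 against nonescalating (11 higher, 1 lower), with adjusted p from 0.000172 for shared neuron markers to 0.033 for D2 neuron markers. The other 6 higher lists were dopamine signalling, GABA receptor, presynaptic vesicle, MAP kinase, and actin and spine genes and those of D2 neurons. None of the 12 held with an estimated correlation (adjusted p = 0.506 for each). Without nonescalating replicate 4 none of the 12 lists passed camera. The adjusted p was then 0.0621 for shared neuron, immediate early, opioid and neuropeptide, and oxidative phosphorylation genes. It was 0.0636 for MAP kinase genes and ran from 0.101 (presynaptic vesicle) to 0.402 (D2 neuron) for the other lists. The medians were then 0.34 for shared neuron, 0.26 for oxidative phosphorylation, 0.46 for opioid and neuropeptide and 0.22 for potassium channel genes. They were -0.37 for astrocyte and 0.26 for immediate early genes. Removal of escalating replicate 2 also lowered the count of lists against nonescalating, but it leaves a single escalating library. In that comparison 1 gene passed without escalating replicate 1 or nonescalating replicate 1 and 2 genes without escalating replicate 2. The median of all genes moved by -0.13 on the log2 scale with median-of-ratios scaling, which was larger than in any other comparison. In escalating against saline, 11 lists passed without saline replicate 3, 1 without saline replicate 1 and 2 without escalating replicate 1, and 1 gene passed without either escalating library. The median of the immediate early genes against nonescalating turned to -0.14 without escalating replicate 1.

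After withdrawal, nonescalating cocaine libraries (n = 8) were compared with saline libraries (n = 6), both groups split over the 2 library sets. Elovl2, which elongates very long chain polyunsaturated fatty acids, had the smallest p, with 22.0 CPM ± 11.7 (SD, n = 8) against 1.74 ± 1.79 (SD, n = 6) and a log2 fold change of 3.62 (SE 0.92, unadjusted p = 0.000443 in edgeR, adjusted p = 1); all 8 cocaine libraries lay above all 6 saline libraries. Of 76 cytosolic ribosomal protein genes 61 had negative fold changes (median -0.17), and Rpl18 (-0.81, SE 0.35, adjusted p = 1) lay below every saline library in 6 of 8. All 8 RNAs of the nuclear-retained list had positive ones (median 0.78), with Malat1 at 20766 CPM ± 9044 (SD, n = 8) against 14031 ± 7331 (SD, n = 6), a log2 fold change of 0.66 (SE 0.46, adjusted p = 1). Of 16 shared medium spiny neuron markers 14 were below 0 (median -0.24), as for the transcription factor gene Meis2 (-0.39, SE 0.26, adjusted p = 1).

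edgeR called 0 of 15854 genes, with 553 at an unadjusted p under 0.05. limma voom called 0 and DESeq2 called 2, Elovl2 and Izumo1, of which 1 had no count in 1 of the groups. The 3 lists passed camera with adjusted p of 0.00029 (ribosomal proteins), 0.0137 (nuclear RNAs) and 0.0204 (shared neuron markers), each 0.798 with an estimated correlation. In library set 1 alone no list passed and the medians turned to 0.10 for ribosomal proteins and -0.22 for nuclear RNAs, while in set 2 alone 5 lists passed. No list passed without library 1818 or 1836 of the saline group or library 1840 of the cocaine group, 1 passed without library 1838, 1839 or 1843, and 6, 8 and 18 passed without libraries 1821, 1837 and 1817.

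The withdrawal period itself was compared within each agent. The groups without withdrawal lie in library set 1 only. Set 2 withdrawal libraries therefore enter these fold changes only after adjustment for the library set, while the CPM means cover both sets unadjusted. In saline animals (withdrawal n = 6, none n = 3) no gene passed. Cacul1 had 71.0 CPM ± 34.9 (SD, n = 6) against 175 ± 110 (SD, n = 3), a log2 fold change of -1.91 (SE 0.46, adjusted p = 0.742), and the zinc finger gene Zfp142 had -2.10 (SE 0.52, adjusted p = 0.742). All 11 microglia genes had negative fold changes (median -2.31), as for Csf1r, the receptor that microglia need to survive, at 9.53 CPM ± 11.9 (SD, n = 6) against 154 ± 226 (SD, n = 3), with -3.37 (SE 1.18, adjusted p = 0.742). In cocaine animals (withdrawal n = 8, none n = 5) the myelin gene Mbp had 150 CPM ± 72.5 (SD, n = 8) against 926 ± 704 (SD, n = 5), a log2 fold change of -2.31 (SE 0.59, adjusted p = 1), and the astrocyte-rich gene Ndrg2 had -1.94 (SE 0.48, adjusted p = 1). In saline animals the fold changes were -2.10 (SE 0.65, adjusted p = 0.742) for Mbp and -1.07 (SE 0.55, adjusted p = 0.768) for Ndrg2. Without withdrawal, Mbp had 1662 CPM in saline replicate 4, against 198 CPM in replicate 1 and 255 CPM in replicate 3. The size of the Mbp fold change in saline animals thus rests largely on 1 library. The difference of the cocaine effects was -0.21 (SE 0.79, adjusted p = 1) for Mbp and -0.87 (SE 0.67, adjusted p = 1) for Ndrg2. Astrocyte genes had negative values in 13 of 14 (median -0.77), oligodendrocyte genes in 9 of 13 (median -0.43), microglia genes in 10 of 11 (median -1.13) and circadian clock genes in 13 of 18 (median -0.21), the last led by Per3 (-1.07, SE 0.40, adjusted p = 1). Chaperone genes had positive values in 24 of 27 (median 0.27), as for Hspd1 (0.63, SE 0.46), oxidative phosphorylation genes in 52 of 73 (median 0.24) and shared neuron markers in 12 of 16 (median 0.29).

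edgeR called 0 of 15854 genes in both, with 1052 (saline) and 440 (cocaine) at an unadjusted p under 0.05. limma voom called 0 in both and DESeq2 30 (18 with no count in 1 of the groups) and 0. Camera called the microglia list in saline (adjusted p = 0.00285, and 0.475 with an estimated correlation), a call that ended without saline replicate 4, and 13 lists passed without saline replicate 3, 10 without library 1817, 4 without 1819 and 3 without 1837. In cocaine animals it called 7 lists with adjusted p from 0.00289 (oligodendrocyte) to 0.0336 (shared neuron markers). With an estimated correlation the adjusted p was 0.483 for the 3 glial lists, 0.36 for clock genes, 0.788 for chaperones and 0.816 for the other two lists. None of the 7 passed without nonescalating replicate 4, which had the low Drd2 level. Its removal changed the medians to -0.30 for microglia, 0.085 for shared neuron and 0.036 for oxidative phosphorylation genes. They were then -0.50 for astrocyte, -0.42 for oligodendrocyte, -0.27 for clock and 0.24 for chaperone genes. By contrast, 17 lists passed without nonescalating replicate 1 or 3, 12 without library 1820, and 4 without 1814 or 1821.

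Whether the cocaine difference depended on withdrawal was tested as the difference of the 2 cocaine effects. No gene and no list passed. Hdac5 (chromosome 11, 102194432 to 102230166, minus strand), a class IIa histone deacetylase gene studied in cocaine reward, had the smallest p, with a log2 difference of -3.37 (SE 0.77, adjusted p = 0.972). Without withdrawal its cocaine effect was a log2 fold change of 1.94 (SE 0.63, adjusted p = 0.719). In withdrawal it was -1.43 (SE 0.43, adjusted p = 1), with 166 CPM ± 118 (SD, n = 8) in nonescalating withdrawal and 463 ± 372 (SD, n = 6) in saline withdrawal. Gabpb2, a transcription factor subunit gene, had a difference of 2.43 (SE 0.64, adjusted p = 0.972). edgeR called 0 of 15854 genes, with 776 at an unadjusted p under 0.05. limma voom called 0 and DESeq2 11, of which 9 had no count in 1 of the groups. Without saline replicate 4 1 list passed. On simulated counts with the spread of these libraries, edgeR was run with 50 genes per size of change. In nonescalating against saline it recovered 0% of genes changed 2-fold, 12% of those changed 4-fold and 36% of those changed 8-fold. In the withdrawal comparison the shares were 4%, 44% and 58%. These genes had a mean log2 CPM of at least 2, so the shares do not cover lower genes. The difference of the cocaine effects was not simulated; the median SE over genes was 1.21 for it, against 0.97 and 0.74 in those comparisons.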

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

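The tests of glial carry-over, of the arrangement of the inputs, of library 1813 alone and of correlation within lists were chosen only after the result was seen. In the saline withdrawal group (n = 6), library 1817 lay far below the others in 4 measures: log2(CPM + 1) of Drd2 was 9.79 against 11.04 in the nearest library, that of Tac1 0.57 against 3.98, the D2 neuron score 6.60 against 7.15 and the shared medium spiny neuron score 8.25 against 9.34. In nonescalating withdrawal (n = 8), library 1843 had no count of Tac1, a value of 0 against 3.45 in the nearest library. These are 5 of 54 groups and measures tested, and chance flags about 1 in 20, or 2.7 here; the measures of library 1817 are related to each other.

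In the 8 immunopurified libraries of set 1 without withdrawal, the vascular genes stood above input by a list median of 3.91 (fry adjusted p = 0.059); their exact two-sided permutation p, 8 libraries against 2, was 0.0222, the smallest that design allows, while for the 8 libraries of set 2 it was 0.133, with the lowest, 3.39, below the saline input at 4.0. Oligodendrocyte genes had a list median of -2.28 (adjusted p = 0.0264 in fry and 0.0986 in camera with an estimated correlation). They thus made up a smaller share than in input, which cannot exclude that some were carried over along with vessels. Against a trend with gene length and GC content stands a vascular list median of 3.42 after its removal. The middle 95% of random lists lay between -0.66 and 0.20. Carry-over of astrocytes stays open, since their median of -0.87 had an adjusted p of 0.205 in fry and 0.337 with an estimated correlation, and so does that of microglia, with a median of -0.050. Weak purification stays open too. In the 16 immunopurified libraries of set 1, Pearson r between the D2 neuron and vascular scores was -0.31 (permutation p = 0.253, adjusted p = 0.659 over 4 relations). Spearman rho there was -0.21 (permutation p = 0.425), and r without the 2 farthest libraries was -0.24. In the 8 of set 2 r was 0.21 (permutation p = 0.704), but rho was -0.12 and r without the 2 farthest libraries -0.43. Use of the Drd2 promoter or transgene in vascular cells may also contribute and was not tested.

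Against the nonescalating group, 12 gene lists passed with escalating and 7 with nonescalating withdrawal. Whether they rest on library 1813 alone (nonescalating replicate 4, with the lowest Drd2) cannot be told apart: without it 0 passed in both comparisons. Of the medians, 12 of 12 and 7 of 7 kept their sign, but 11 of 12 and 6 of 7 became smaller. Of these, 0 and 3 fell under 1/3 of their size. Removal of escalating replicate 2 also lowered the number of lists in escalating against nonescalating. It leaves a single escalating library, so that fit takes its spread from the other groups and cannot weigh library 1813 against another library. Correlation among the genes of a list stays a candidate explanation, since 0 passed with an estimated correlation. Escalation of intake and withdrawal, which the design names, stay open, though 0 genes passed in either comparison.

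The vascular score of the withdrawal libraries was 6.76 ± 0.75 (SD, n = 6) in set 1 and 4.56 ± 0.92 (SD, n = 8) in set 2, a difference of -2.21 (exact permutation p = 0.00233, adjusted p = 0.0197 over 37 lists). Of the 13 vascular genes, all listed in the files of both sets, 100% were lower in set 2. These genes make up the score itself, so the count cannot decide whether different gene lists or annotations contribute. A stronger purification of D2 neuron RNA in set 2 had no support in direction, with a D2 score difference of -0.22, but that lay within the spread (exact permutation p = 0.368), so it stays open. Library size cannot be told apart. Between log2 counts and the vascular score, r was -0.26 in set 1 (n = 16, permutation p = 0.329). There rho was -0.16 (permutation p = 0.558), and r without 2 libraries was -0.41. In set 2 r was 0.21 (n = 8, permutation p = 0.584), rho was 0.26 and r without 2 libraries was 0.066. No biological explanation was tested, since both sets hold saline and cocaine libraries.

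Splits were made in the 5 comparisons with at least 3 libraries per group. Chance cannot be excluded for the counts of genes at an unadjusted p under 0.05 in any of the 5. For lists the same holds, but they were not compared for the difference of the cocaine effects, where 0 passed. Each count of splits below includes the true split. In nonescalating against saline, 28 of 56 splits of the libraries gave as many genes (real 1068, highest other 3584) and 47 of 56 as many lists (real 2, highest other 18). In nonescalating withdrawal against saline withdrawal, 52 of 100 splits gave as many genes (553, highest other 1575) and 57 of 100 as many lists (3, highest other 20). In nonescalating withdrawal against nonescalating, 50 of 56 gave as many genes (440, highest other 1609) and 40 of 56 as many lists (7, highest other 21). For the difference of the cocaine effects, 70 of 100 gave as many genes (776, highest other 3692). In saline withdrawal against saline the 20 splits are too few to exclude chance at any count. There 10 were as large for genes (1052, highest other 2699) and 19 for lists (1, highest other 20). The most genes past the threshold in another split were 154 in nonescalating against saline (libraries 1808, 1810 and 1812 against the rest), 9 in saline withdrawal against saline and 320 for the difference of the cocaine effects. Libraries 1808, 1810 and 1812 had 29.7%, 34.0% and 35.3% of records in no feature. The other saline and nonescalating libraries had 45.6% to 62.5%. Malat1 stood at 7452, 12963 and 8930 CPM in these libraries, against 26679 to 76828 CPM in the others. This difference cut across saline and nonescalating. Whether it accounts for the calls of that split, and what sets the libraries of the other splits apart, was not tested.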

How the results depend on the processing

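The vascular covariate, the larger sets of immunopurified libraries against input, the removal of libraries 1806, 1813 and 1843, and the list tests with the block, within a library set or without 1 library were chosen only after the result was seen. Depth limits low genes: 3 counts correspond to up to 2.19 CPM in the shallowest library. Of the values of named genes under an alternative, 3867 kept direction and side of the threshold, 116 gained a call, 30 lost it and 31 changed sign. Only 12 genes were named for passing, and most of the others had not passed in the main fit. Those had no call to lose, so the 3867 are no measure of how stable the calls were. Of the values of lists, which had all passed in the main fit, 437 kept direction and call, 210 lost the call and 6 changed sign. For these and the counts that follow, the cause was not tested. Taking the nonescalating libraries as withdrawal libraries, against saline withdrawal of set 1, edgeR called 0 genes, with 564 at an unadjusted p under 0.05.

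Against 0 genes with edgeR, DESeq2 called 34 genes in nonescalating against saline, 143 in escalating against saline, 225 in escalating against nonescalating, 2 in nonescalating withdrawal against saline withdrawal, 30 in saline withdrawal against saline and 11 for the difference of cocaine effects. limma voom called 8 and a stricter filter 1 gene (Ap2a1) in escalating against nonescalating. For immunopurified against input RNA, against 38, DESeq2 called 757, no filter 132, all 24 immunopurified libraries 150 (105 higher, 45 lower) and the 16 of set 1 160 (121 higher, 39 lower).

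Of gene lists, with an estimated correlation 0 passed in nonescalating against saline, escalating against nonescalating, nonescalating withdrawal against saline withdrawal, saline withdrawal against saline, nonescalating withdrawal against nonescalating, and immunopurified against input; fry called 0 in the first 5 of these and 5 in the last. With the vascular covariate 0 passed in nonescalating against saline, 0 in the withdrawal comparison and 2 in saline withdrawal against saline. With only the groups compared, 0 passed in nonescalating against saline. Without libraries 1806, 1813 and 1843, 1 passed in escalating against saline, 0 in escalating against nonescalating and 0 in nonescalating withdrawal against nonescalating. In nonescalating withdrawal against saline withdrawal, 0 passed in set 1 alone and 5 in set 2 alone.

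With 1 library left out, the count of genes ran from 0 to 0 in nonescalating against saline, both withdrawal comparisons within an agent, nonescalating withdrawal against saline withdrawal and the difference, from 0 to 1 in escalating against saline, from 0 to 2 in escalating against nonescalating, and from 1 (without either input) to 252 (without saline replicate 3) against input. The count of lists ran from 0 to 15 in nonescalating against saline, 0 to 11 in escalating against saline, 0 to 18 in escalating against nonescalating, 0 to 18 in nonescalating withdrawal against saline withdrawal, 0 to 13 in saline withdrawal against saline, 0 to 17 in nonescalating withdrawal against nonescalating, 0 to 1 for the difference and 11 to 18 against input.

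Whether the replicate numbers pair the libraries stays open: correlations of same-numbered libraries ran from -0.13 to 0.27. In nonescalating withdrawal against saline withdrawal the 5 same-numbered pairs ran from 0.012 to 0.27, against a median of -0.019 for other numbers. In nonescalating withdrawal against nonescalating the 3 same-numbered pairs ran from -0.13 to -0.075, against a median of 0.050 for other numbers. With the replicate block, 0 genes passed in each of the 6 comparisons fitted; 0 lists passed in saline withdrawal against saline, 12 in nonescalating withdrawal against nonescalating and 1 for the difference, and the immediate early gene median in escalating against nonescalating was -0.021. No paired fit was made for escalating against saline, which share 1 number.

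Values that changed sign were, in nonescalating vs saline, the shared neuron list at 0.051 and Bcl11b at 0.092 with the vascular covariate. With 1 library left out the list ran from -0.50 to 0.33, Scn4b from -1.04 to 0.12, Pde10a from -0.79 to 0.16 and Bcl11b from -0.92 to 0.75, each positive without saline replicate 3. Pard6g in escalating vs saline ran from -3.69 to 8.32, and Pard6g in escalating vs nonescalating from -3.88 to 8.11. There the immediate early list ran from -0.14 to 0.80, Adora2a in escalating vs nonescalating from -0.0092 to 0.94, Junb in escalating vs nonescalating from -1.96 to 4.37 and Npy from -2.27 to 5.33, each negative without escalating replicate 1. Drd5 in escalating vs nonescalating ran from -2.05 to 7.79, Sv2b from -0.43 to 1.54 and Dusp14 from -0.41 to 2.18, each negative without escalating replicate 2; Drd5 was -0.26 with limma voom and Agt 0.18 with the non-neuronal covariate. In library set 1 alone the withdrawal comparison gave nuclear RNAs -0.22, ribosomal proteins 0.10, Adcy5 0.072, Gng7 0.20 and Miat -0.46. Tmem119 in saline withdrawal vs saline ran from -7.23 to 0.18 and Aif1 in saline withdrawal vs saline from -7.45 to 1.09, positive without saline replicate 4, and Aif1 was 2.20 with the non-neuronal covariate, which gave Agt 0.28 and C1qb 0.12 in nonescalating withdrawal vs nonescalating. In IP vs input, Slc5a7 ran from -2.31 to 0.42, the latter without the nonescalating input. Fos in IP vs input ran from -1.95 to 2.89, the latter without the saline input, and was 0.47 without libraries 1806, 1813 and 1843, 1.44 with 24 and 1.13 with 16 immunopurified libraries.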

Other observations

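The test of differences between library sets over all lists was chosen only after the vascular difference was seen. Of 17 interferon and immune genes, 16 had positive fold changes over input in the immunopurified libraries (list adjusted p = 0.181 with an estimated correlation), among them the MHC class I gene H2-K1 at 230 CPM ± 277 (SD, n = 8) against 7.49 CPM, with a log2 fold change of 4.85 (SE 1.17, edgeR adjusted p = 0.0822), and Ifitm3 at 77.9 CPM ± 59.0 (SD, n = 8) against 8.12 CPM, with 3.28 (SE 0.91, edgeR adjusted p = 0.142). Neither passed the threshold, and both were above both inputs in 8 of 8 libraries.

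Between the withdrawal libraries of set 1 (n = 6) and set 2 (n = 8), scores were also lower in set 2 for oligodendrocyte precursor genes (-1.27, exact permutation p = 0.002, adjusted p = 0.0197), immediate early genes (-0.96, exact permutation p = 0.00366, adjusted p = 0.0226), extracellular matrix genes (-0.69, exact permutation p = 0.00266, adjusted p = 0.0197), glucocorticoid responsive genes (-0.48, exact permutation p = 0.00133, adjusted p = 0.0197), chromatin regulators (-0.42, exact permutation p = 0.000999, adjusted p = 0.0197), chaperones (-0.45, exact permutation p = 0.00866, adjusted p = 0.0383) and interferon and immune genes (-1.83, exact permutation p = 0.00932, adjusted p = 0.0383). Sex-linked genes were higher by 0.78 (exact permutation p = 0.00866, adjusted p = 0.0383). This mean over the list does not tell which of its genes moved. The withdrawal libraries of set 2 were also shallower, with a difference in mean log2 gene counts of -1.48 (set 2 minus set 1). Whether depth moves these scores was not tested. Xist, which is transcribed from the inactive X chromosome, had 0 to 3.03 CPM in the withdrawal libraries of set 1. In set 2 only libraries 1838 (1.03 CPM) and 1839 (1.99 CPM) lay in that range. The others had at least 7.70 CPM, with 146 CPM in saline withdrawal library 1837. The Y-linked gene Ddx3y had 18.2 to 38.2 CPM in set 1 and 22.7 to 53.4 CPM in set 2. Y-linked Eif2s3y had 8.05 to 38.8 CPM in set 1 and 4.39 to 56.9 CPM in set 2. Whether the sets differ in the sex of their animals was not tested.

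A shared cocaine response with and without withdrawal was tested as the correlation of the 2 cocaine effects across genes, which are not independent replicates. Pearson r was 0.074. Of 100 labellings of the libraries within sets, the true labelling included, 23 gave as large a value (others: median -0.0017, highest 0.37). A shared response thus could not be told apart from chance.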
